A study of Saccharomyces cerevisiae with 42 samples.

How the data were processed

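The series holds 42 tiling arrays of chromatin immunoprecipitation (ChIP-chip) from Saccharomyces cerevisiae, with 7 strains, 2 antibodies and 3 replicates in each of 14 groups. The strains are a wild type that lacks BAR1, the protease that degrades α-factor, and the deletions isw1, chd1, isw1 chd1, set2, isw1 set2 and chd1 set2. The antibodies recognise acetylated histone H4 (AcH4) and histone H3. Per the labels' protocols, cultures in YPD reached an OD of 0.4, were arrested with 2 µM α-factor for 4 h and were cross-linked before immunoprecipitation. The recovered DNA was amplified through in vitro transcription and labelled as RNA, and each array compared the immunoprecipitate in Cy5 with its input in Cy3, with no dye swap. The labels call the replicates biological. The number of arrays limits the precision.

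Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, and the deposited processed intensity of each channel had its background subtracted, was detrended and was dye-normalized by a linear factor per channel. The deposited log10 ratio is that of the same processed signals, per the file headers, and was used to check them. The deposited series value table holds log2 ratios of the same arrays with a median near 0 and a spread scaled array by array. This was judged by a comparison with the scanner values, since the method of scaling is not given in the sources used here. The lowest r with the scanner ratios was 0.94, for isw1 AcH4 replicate 2. That column is thus not a plain rescaling of its scan, and the value table results for isw1 rest in part on it. The table's direction equalled that of the scanner ratios, and its column medians lay between -0.01 and 0.03. The submitters' processing notes name R 2.13.0. Coordinates are those of the files, in build sacCer1.

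The main values were log2 of processed Cy5 over Cy3, centred on the median of each array, with control spots and outlier spots left out and no loess or quantile step. Of 60647 non-control probes, 55293 carried the name of 1 nuclear protein-coding gene in the files, and 5632 distinct names had a single locus tag among the gene names given. The tract of a gene in the files is not its coding region alone. Between tandem neighbours the intergenic probes carry the downstream gene's name, and 96.2% of divergent pairs but 0.562% of tandem pairs had an intergenic tract of their own. No probe sequences were used here, so probes that match several places could not be found. A gene value was the mean of at least 2 probes, available for 5497 genes. The probes of each tract were divided by their order into a 5' part and a 3' part with equal numbers of probes. The middle probe of an odd number was left out. The profile along genes used tracts of at least 500 bp. Its promoter values came from probes up to 500 bp upstream, for genes with a separate upstream intergenic tract. Such tracts lay almost only between divergent genes, and 1 tract could serve both of its genes. Promoters of most tandem genes thus fell in the 5' part. On every array at least 98.0% of probes were well above background in both channels, and no spot was saturated.

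Gene values of all arrays were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and tables were handled with data.table in version 1.17.8. The change in AcH4 per H3 was the mutant difference AcH4 minus H3 less the wild type difference. The H3 comparison was mutant minus wild type. The interaction was the change in a double mutant less the sum of the changes in both single mutants. Adjusted p values are those of Benjamini and Hochberg, with a threshold of 0.05, and errors of changes are standard errors of the fit with 3 arrays per group. Where arrays of 1 gene disagree, only their mean enters. Profile values, taken as AcH4 minus H3 of the same replicate number, were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over all lists and mutants together. Genes were not matched on tract length in these tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

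The lists, fixed before the data were examined, were reporters of initiation inside genes, pheromone response, histones, ribosomal proteins, ribosome biogenesis, glycolysis, galactose use, heat shock, meiosis and sporulation, amino acid synthesis, respiration, phosphate response, G1/S and G2/M cell cycle genes, the Set2 and Rpd3S pathway, chromatin remodelers, the PAU and COS subtelomeric families, 4 classes of tract length and genes within 20 kb of a chromosome end. The rule for named genes was also fixed then. It took, per mutant, the 8 largest rises and 4 largest falls in AcH4 per H3 among called genes with at least 4 probes, a standard symbol and every mutant replicate beyond every wild type replicate. It added all initiation reporters, up to 2 called members of each other list, 4 rises and 4 falls in H3, 4 rises and 2 falls in the 3' minus 5' difference, and 3 each way per interaction. The report prints part of that set. Deletion markers, mitochondrial genes and genes with missing input were not named, the last of these an exception added after the data were seen.

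The steps were tested on simulated data. For set2 against wild type in AcH4 per H3, over 5495 genes, the fit recovered 68% of changes of 0.5 and 97% of changes of 1 (log2). For H3 it recovered 92% and 100% (5495 genes). For the isw1 by set2 interaction it recovered 16% and 82% (5494 genes), and for the 3' minus 5' difference 7% and 67% (4983 genes). Of 200 random lists, 3 had p under 0.05 in camera. The simulated genes varied independently, so this does not test the preset correlation. The alternatives tried were normexp background correction, loess within arrays, quantile normalization per antibody, equal array spread, the series value table, dim probes left out, medians of probes, at least 4 probes, trend and robust moderation, the compared strains alone, AcH4 over input alone, scan sessions or dates as blocks, the replicate number as a block, and each replicate left out. The files hold 9 scan sessions on 7 days, and arrays of 1 session were treated as 1 slide. Wild type AcH4 arrays shared no session with other strains, and a session term could be fitted for 2 results, H3 in isw1 and H3 in chd1.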

Results

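Acetylated histone H4 (AcH4) and histone H3 were mapped by ChIP-chip in 7 strains of budding yeast arrested with α-factor, with 3 arrays per strain and antibody. Isw1 and Chd1 are ATP-dependent chromatin remodelers, and Set2 is a histone H3 methyltransferase that travels with elongating RNA polymerase II. The comparisons ask how AcH4 per H3 and H3 itself differ over genes when these factors are lost singly or in pairs. Between 99.0% and 99.8% of probes per array were well above background in the input channel, and between 98.0% and 99.7% in the immunoprecipitate. Replicates of a group correlated across genes with r between 0.81 and 0.99, lowest for chd1 AcH4, and no replicates of a group held identical values. Values are log2 ratios centred on each array's median. A shift shared by all probes of an array would thus not show, and all rises and falls are relative to that median. The wild type AcH4 arrays were scanned in sessions of their own, so scan session and strain cannot be told apart for AcH4 per H3.

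The input signal followed the labels of the strains. Over ISW1 (chromosome 2, 708159 to 711358) the input averaged -4.46 in the 3 isw1 strains and 0.30 in the other 4. It stood at -2.66 in isw1, where its highest array reached -1.66, -5.97 in isw1 chd1 and -4.74 in isw1 set2. Over CHD1 (chromosome 5, 505504 to 509804) it averaged -6.31 and -0.19, and over SET2 (chromosome 10, 102375 to 104310) -6.02 and 0.06. No array of a deleted strain reached the lowest array of the others (exact permutation p = 0.0286 for each gene, 3 against 4 strains). BAR1 lacked input in all 7 strains, between -5.65 and -3.91.

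In wild type cells AcH4 per H3 was highest over the promoters measured, and lower over the 3' part of genes than over the 5' part. These promoters were those of 2332 genes with a separate upstream intergenic tract, mostly between divergent genes. AcH4 per H3 averaged 1.13 ± 0.15 (SD, n = 3) over them, 0.49 ± 0.07 over the 5' part of 4968 genes and -0.14 ± 0.04 over the 3' part. In set2 cells the same regions averaged 0.27 ± 0.0099, -0.0016 ± 0.00084 and 0.033 ± 0.0059, and in chd1 set2 cells 0.12 ± 0.0093, -0.077 ± 0.0047 and 0.038 ± 0.019. In isw1 set2 cells they averaged 0.19 ± 0.011, -0.018 ± 0.0048 and 0.0029 ± 0.0050. The chd1 strain had 0.77 ± 0.14 over promoters and 0.05 ± 0.02 over the 3' part, isw1 chd1 had 0.93 ± 0.08 and 0.08 ± 0.03, and isw1 had 0.94 ± 0.08 and 0.01 ± 0.02. The 3' part was higher than in wild type by 0.14 to 0.22 in all 6 mutants, and no replicate reached those of wild type. The exact permutation p was 0.1 for each, the smallest that 3 against 3 allow (adjusted p = 0.129 over 18 comparisons). Promoter means lay below wild type in all 6, with exact permutation p = 0.1 (adjusted p = 0.129) in chd1 and the 3 set2 strains and p = 0.2 (adjusted p = 0.212) in isw1 and isw1 chd1. The 3' differences ran from 0.16 to 0.40 with normexp, from 0.22 to 0.39 over genes of at least 1000 bp and from 0.092 to 0.20 with equal array spread, chosen after seeing the data, each with exact permutation p = 0.1. In AcH4 over input without H3 the 3' difference was smaller, at 0.081 in isw1, 0.024 in chd1, 0.036 in isw1 chd1, 0.069 in set2, 0.036 in isw1 set2 and -0.037 in chd1 set2. There the replicates of chd1 and isw1 chd1 were no longer apart from those of wild type (exact permutation p = 0.2 for each). The promoter fall kept full separation in the 3 set2 strains under these 4 alternatives. In chd1 it was -0.23 with equal array spread (exact permutation p = 0.3) and -0.27 in AcH4 over input alone (p = 0.2). In isw1 it was -0.071 with equal array spread (exact permutation p = 0.7), but -0.26 with normexp and -0.20 in AcH4 over input alone (p = 0.1 for each). In isw1 chd1 it was -0.11 with equal array spread (exact permutation p = 0.6) and -0.050 with normexp (p = 0.5). The median immunoprecipitate signal of the AcH4 arrays ran from 30763 to 36118 in the 3 set2 strains, from 11788 to 13833 in isw1 chd1, from 1125 to 5634 in wild type and from 366 to 1545 in isw1 and chd1.

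**Figure D1:**
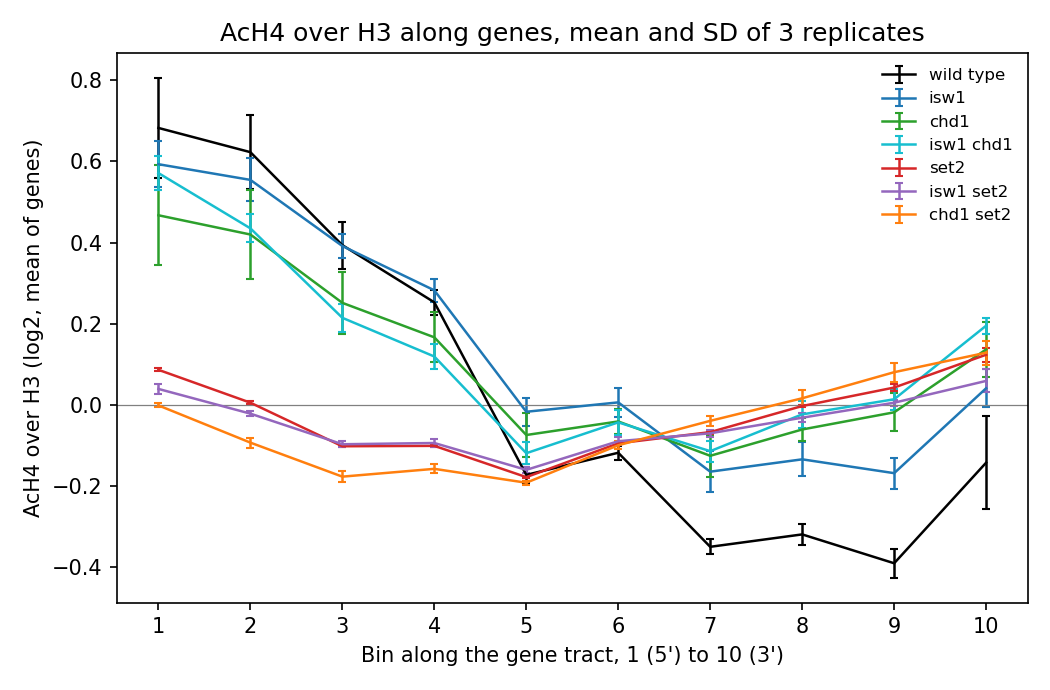
AcH4 over H3 (log2, vertical axis) in 10 bins of the gene tract from 5' to 3' (horizontal axis) for the 7 strains, with lines through means of 3 replicates and bars of 1 SD. In bin 1 wild type stood at 0.68 ± 0.12 and set2 at 0.086 ± 0.0037, and in bin 9 wild type stood at -0.39 ± 0.04 and set2 at 0.04 ± 0.01.

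In the isw1 strain the named genes with the largest gains in AcH4 per H3 included LDS1, SPS4 and MUM3. LDS1, a gene of the spore wall (chromosome 1, 118600 to 119462), rose by 2.03 ± 0.19 (log2, SE, n = 3), which is 4.10-fold. SPS4, induced in sporulation, rose by 1.96 ± 0.23, MUM3 by 1.65 ± 0.13, the ubiquitin ligase gene HUL4 by 1.52 ± 0.12 and SAS4, of a histone acetyltransferase complex, by 1.48 ± 0.18. The falls among named genes included the sulfatase gene BDS1 (-1.45 ± 0.14), CAK1, which encodes the kinase that activates Cdc28 (-0.92 ± 0.14), and IMD2, an IMP dehydrogenase gene (-0.92 ± 0.16). Of 5495 genes, 1667 passed the test, 1064 up and 603 down. The split was 506 up and 482 down with quantile normalization, 623 and 134 with equal array spread, 773 and 158 in the series value table and 1218 and 1090 in AcH4 over input alone. The count was 565 with loess and 1093 without isw1 replicate 3.

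Several lists passed camera in isw1 at the preset correlation, and none did with an estimated correlation. Of 47 meiosis and sporulation genes, 20 rose and 2 fell (22 and 4 adjusted over the list alone), with SPS1, a sporulation kinase, up by 1.23 ± 0.14. In camera the list had adjusted p = 9.03e-05, and adjusted p = 0.275 with an estimated correlation. Of 26 chromatin remodeler genes, 15 rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.000722, and adjusted p = 0.244 with an estimated correlation). ITC1 stood at 0.91 ± 0.11 and FUN30 at 0.74 ± 0.13. Of 31 G1/S genes, 15 rose and 1 fell, the same adjusted over the list alone (adjusted p = 9.47e-05, and adjusted p = 0.0782 with an estimated correlation). The checkpoint kinase gene RAD53 rose by 0.96 ± 0.11 and the polymerase gene POL2 by 0.91 ± 0.10. Of the reporters of initiation inside genes, 5 of 8 rose and SYF1 fell by 0.36 ± 0.11 (6 and 1 adjusted over the list alone; adjusted p = 0.00945, and adjusted p = 0.178 with an estimated correlation). AVO1 rose by 0.62 ± 0.09, SMC3 by 0.73 ± 0.12, VPS72 by 0.64 ± 0.19, STE11 by 0.60 ± 0.09 and SPB4 by 0.36 ± 0.13. The calls of VPS72, SPB4 and SYF1 were lost in 6, 8 and 6 of 20 alternatives. VPS72 stood at 0.22 with loess, 0.50 without wild type replicate 2 and 0.52 without isw1 replicate 3. SPB4 stood at 0.061 in AcH4 over input alone, 0.37 and 0.28 without wild type replicates 1 and 2, and 0.31 and 0.40 without isw1 replicates 1 and 3. SYF1 stood at -0.17 in AcH4 over input alone and -0.31 without isw1 replicate 1. PCA1 (0.22 ± 0.10) and OMS1 (0.17 ± 0.16) were not called. PCA1 passed at 0.49 with medians of probes, 0.33 in AcH4 over input alone and 0.23 with the session as a random block, and stood at -0.028 with loess. OMS1 stood at -0.14 with loess, -0.023 with quantile normalization and -0.045 in AcH4 over input alone. Of 132 ribosomal protein genes, 39 fell and 0 rose (38 and 0 adjusted over the list alone; adjusted p = 4.32e-10, and adjusted p = 0.154 with an estimated correlation). RPS22A stood at -0.89 ± 0.20 and RPL15A at -0.67 ± 0.17, whose call was lost in 2 of 19 alternatives (-0.46 with equal array spread and -0.43 in the value table). Of 23 PAU and COS genes, 9 rose, the same adjusted over the list alone, with PAU7 at 1.16 ± 0.10 (adjusted p = 0.00987, and adjusted p = 0.326 with an estimated correlation). Of 14 phosphate response genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.038, and adjusted p = 0.248 with an estimated correlation). SPL2 stood at -0.73 ± 0.16 and PHO5, the secreted acid phosphatase gene, at -0.59 ± 0.13. Of 7 histone genes 3 fell and 1 rose, the same adjusted over the list alone, with HTB2 at -0.70 ± 0.21, whose call was lost in 5 of 19 alternatives (-0.34 with loess, -0.30 with equal array spread, -0.31 in the value table, -0.51 with medians of probes and -0.57 without wild type replicate 3). That list did not pass the test (adjusted p = 0.168), and its median against all genes turned from -0.30 to 0.07 with loess.

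Along genes, 727 of 4986 tracts in isw1 gained AcH4 per H3 in the 3' part against the 5' part, and 144 lost it. MRE11, a gene of double-strand break repair, gained 2.09 ± 0.19, CFT2, of the mRNA cleavage complex, 2.04 ± 0.28 and the chaperone gene SSA4 2.01 ± 0.19. POX1, the peroxisomal fatty acid oxidase gene, changed by -2.95 ± 0.28. With loess the split was 163 up and 63 down, and the total was 304 with equal array spread. The total of 871 became 567 without wild type replicate 2, 576 without isw1 replicate 1 and 485 without isw1 replicate 3.

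In isw1 the H3 level of the karyogamy gene KAR5 rose by 0.46 ± 0.09 and that of BDS1 by 0.51 ± 0.10. APC9 (-0.85 ± 0.16), SPS4 (-0.83 ± 0.16) and RNA15, of the mRNA cleavage complex (-0.76 ± 0.08), fell. Of 22 alternatives the call was lost in 8 at KAR5, 4 at BDS1, 5 at SPS4 and 2 at APC9, and without wild type replicate 2 KAR5, BDS1 and SPS4 stood at 0.45, 0.49 and -0.67. The lowest size at KAR5 was 0.33, in the value table, and at APC9 -0.33, with normexp. In chd1 FIG2, a cell wall adhesin of mating cells, rose by 0.75 ± 0.12 and AGA1, the anchor of a-agglutinin, by 0.62 ± 0.13. LCL1 (-1.53 ± 0.21), APC9 (-1.03 ± 0.16) and CTR9, of the Paf1 complex (-0.96 ± 0.10), fell. The chd1 call was lost in 6 of 21 alternatives at FIG2 (0.37 to 0.86), in 8 at AGA1 (0.35 to 0.80, and 0.46 without wild type replicate 2) and in 1 at APC9 (-0.41 with normexp). In isw1 329 genes passed the test, 68 up and 261 down (92 and 117 with normexp, 112 and 144 with quantile normalization). In chd1 381 genes passed, 73 up and 308 down (128 and 182 with quantile normalization). With the scan session as a block 26 and 33 genes passed, and 4 within session 1, which held 1 isw1 H3 array with the 3 wild type H3 arrays and no H3 array of chd1. With the session as a random block 546 and 875 passed. The isw1 count was 65, 14 and 973 without wild type replicate 1, 2 and 3 and 123, 73 and 147 without isw1 replicate 1, 2 and 3. The chd1 count was 177, 50 and 1086 without those of wild type and 188 and 189 without chd1 replicate 1 and 2.

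In the chd1 strain AcH4 per H3 rose over CTR9 by 2.10 ± 0.14 (log2, SE, n = 3; chromosome 15, 49661 to 52587). The spore gene ADY3 rose by 1.77 ± 0.16, and ARP8, of the INO80 remodeler, by 1.73 ± 0.10. The chitin synthase gene CHS1 rose by 1.68 ± 0.23 and STE6, the exporter of a-factor, by 1.57 ± 0.23. ADE12, of AMP synthesis, fell by 1.15 ± 0.13, the cell wall gene PIR5 by 1.17 ± 0.16 and the mitochondrial carrier gene YMC1 by 1.09 ± 0.20. Of 5495 genes, 2913 passed the test, 1339 up and 1574 down. The split was 861 up and 1556 down with quantile normalization, 1085 and 699 with equal array spread and 1160 and 802 in the series value table, and the total was 1512 with loess. Along genes, 1828 of 4986 tracts gained in the 3' part against the 5' part and 283 lost. The gains were led by CFT2 (2.54 ± 0.28), MDL1 (2.50 ± 0.17) and the DNA ligase gene CDC9 (2.28 ± 0.17). In AcH4 over input alone 1307 gained and 442 lost. The total of 2111 was 1166 with loess and 973 over the genes with an upstream tract of their own, a smaller set chosen after seeing the data.

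Pheromone genes rose in chd1, 19 up and 1 down of 29 (19 and 2 adjusted over the list alone), with FUS2, of cell fusion, at 1.46 ± 0.21 beside STE6 (adjusted p = 3.15e-05, and adjusted p = 0.275 with an estimated correlation). Of 26 chromatin remodeler genes, 16 rose and 2 fell, the same adjusted over the list alone (adjusted p = 2.75e-06, and adjusted p = 0.123 with an estimated correlation). INO80 rose by 1.46 ± 0.16 and SNF2 by 1.26 ± 0.13. Of the 8 initiation reporters 7 rose, the same adjusted over the list alone (adjusted p = 0.00541, and adjusted p = 0.158 with an estimated correlation). VPS72 rose by 1.05 ± 0.19, SMC3 by 1.00 ± 0.12, AVO1 by 0.64 ± 0.09 and OMS1 by 0.54 ± 0.16. PCA1 rose by 0.34 ± 0.10, SPB4 by 0.31 ± 0.13 and STE11 by 0.25 ± 0.09. The calls of PCA1, SPB4, STE11, OMS1 and AVO1 were lost in 5, 10, 8, 4 and 1 of 20 alternatives, with lowest values of 0.031, 0.020, 0.034, 0.12 and 0.21. SPB4 was not called without wild type replicate 1 or 2 (0.32 and 0.23) or chd1 replicate 1, 2 or 3 (0.33, 0.35 and 0.26). STE11 was not called without wild type replicate 3 (0.22) or chd1 replicate 1 or 2 (0.24 and 0.21), nor was OMS1 without wild type replicate 2 (0.39). SYF1 stood at -0.15 ± 0.11, was not called, and was 0.0044 without chd1 replicate 1. Of 19 glycolysis genes 10 fell, the same adjusted over the list alone, with TDH1 at -1.06 ± 0.20 (adjusted p = 0.0322, and adjusted p = 0.381 with an estimated correlation). Of 41 amino acid synthesis genes 19 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.0297, and adjusted p = 0.452 with an estimated correlation). ARO4 stood at -1.07 ± 0.18 and LYS20 at -1.02 ± 0.17. Of 23 PAU and COS genes 10 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0479, and adjusted p = 0.415 with an estimated correlation), but their median against all genes turned from 0.40 to -0.09 with quantile normalization. The heat shock list had 7 up and 3 down of 22, the same adjusted over the list alone, with SSA3 at 1.02 ± 0.11. Ribosome biogenesis had 13 up and 3 down of 40 (12 and 3 adjusted over the list alone), with NOP14 at 1.46 ± 0.16. Galactose use had 0 up and 3 down of 9 (0 and 0 adjusted over the list alone). These 3 lists did not pass (adjusted p = 0.1, 0.0986 and 0.696). The galactose list's test pointed down, while its median lay above that of all genes by 0.01, and at -0.25 in the series value table.

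In the isw1 chd1 strain the gains among named genes included LDS1 (2.51 ± 0.19), ADY3 (1.95 ± 0.16) and the DNA repair genes RAD54 (1.83 ± 0.09; log2, SE, n = 3; chromosome 7, 193785 to 196347) and RAD2 (1.76 ± 0.14). The falls included FIG2 (-2.43 ± 0.18; chromosome 3, 266880 to 272247), AGA1 (-1.72 ± 0.18; chromosome 14, 703228 to 705820) and RRT8 (-1.63 ± 0.17). At FIG2 and AGA1 H3 itself rose by 3.39 ± 0.12 and 2.71 ± 0.13, and AcH4 over input alone was higher than in wild type, by 0.97 and 0.99. With normexp H3 rose by 0.93 and 0.90, still past the threshold, and AcH4 per H3 stood at -0.080 over FIG2 and 0.0068 over AGA1, with neither called. The median of all genes moved there from -0.03 to 0.13. HSP150, a cell wall gene, and KAR5 gained H3 by 1.36 ± 0.11 and 1.11 ± 0.09, and LCL1 (-1.60 ± 0.21) and PXR1 (-1.44 ± 0.18) lost it. Of 5494 genes, 2773 passed in AcH4 per H3, 1398 up and 1375 down (1797 and 867 with normexp). H3 was called at 2105 genes, 807 up and 1298 down (970 and 1005 with quantile normalization), and at 1145 without wild type replicate 2. Along genes 1922 tracts gained in the 3' part against the 5' part and 406 lost (1519 and 981 in AcH4 over input alone). In this difference NPR2 stood at 3.04 ± 0.29, CFT2 at 2.84 ± 0.28 and AGP2 at 2.74 ± 0.21.

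Among the lists in isw1 chd1, 7 of 8 initiation reporters rose, the same adjusted over the list alone, with adjusted p = 0.000215, and adjusted p = 0.0903 with an estimated correlation. VPS72 rose by 1.30 ± 0.19, AVO1 by 1.16 ± 0.09, SMC3 by 0.82 ± 0.12 and PCA1 by 0.77 ± 0.10. STE11 rose by 0.66 ± 0.09, SPB4 by 0.51 ± 0.13 and OMS1 by 0.41 ± 0.16, and SYF1 (0.17 ± 0.11) was not called. SYF1 passed at 0.32 with normexp and 0.30 in AcH4 over input alone. Of 20 alternatives 9 kept the call of OMS1, which stood at 0.18 with normexp, -0.026 in AcH4 over input alone, 0.26 without wild type replicate 2 and at 0.43 and 0.35 without isw1 chd1 replicates 1 and 3, and 18 kept that of SPB4, which stood at -0.14 in AcH4 over input alone. Of 19 glycolysis genes 12 fell (14 adjusted over the list alone; adjusted p = 0.000118, and adjusted p = 0.158 with an estimated correlation). The hexokinase gene HXK1 stood at -1.03 ± 0.10 and the phosphofructokinase gene PFK1 at -0.91 ± 0.09. Of 35 respiration genes 14 fell and 1 rose, the same adjusted over the list alone, with COX12 at -1.13 ± 0.19 (adjusted p = 0.0027, and adjusted p = 0.149 with an estimated correlation). Of 14 phosphate response genes 7 fell and 1 rose, the same adjusted over the list alone, with PHO5 at -0.98 ± 0.13 (adjusted p = 0.046, and adjusted p = 0.255 with an estimated correlation). The pheromone list had 6 up and 9 down of 29, the same adjusted over the list alone, and did not pass (adjusted p = 0.538). Its median lay 0.13 above that of all genes while its mean and test pointed down, and with equal array spread the median lay at -0.29.

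The isw1 by chd1 interaction was low over CHS1 (-2.21 ± 0.32, SE, n = 3 per strain), between -2.57 and -1.51 in all alternatives run. It stood at -2.89 ± 0.25 over FIG2, but at -0.70 with normexp and -0.21 in AcH4 over input alone, where the call was lost. Its highest named values were at the mitochondrial ribosomal gene MRPL20 (1.33 ± 0.24) and CAK1 (1.32 ± 0.20). It passed the test at 1633 genes, 697 up and 936 down. The split was 1430 and 757 with normexp, 652 and 486 with quantile normalization, 299 and 653 with equal array spread, 406 and 873 in the series value table and 1532 and 1253 in AcH4 over input alone. The total was 741 with loess, 1021 without chd1 replicate 1 and 2460 without chd1 replicate 3.

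In the set2 strain AcH4 per H3, relative to the array medians, was lower than in wild type at 2804 genes and higher at 1288. In this strain, and in isw1 set2 and chd1 set2, the median of all genes moved by -0.35, -0.37 and -0.37 against wild type. Over the 5 other scalings it moved by -0.28 to -0.21 in set2, -0.31 to -0.24 in isw1 set2 and -0.29 to -0.23 in chd1 set2. The calcium channel gene CCH1 (chromosome 7, 924757 to 930816) rose by 2.34 ± 0.14 (log2, SE, n = 3), NFT1 by 2.21 ± 0.15, and the sorting nexin gene VPS5 by 2.19 ± 0.16. The RecQ helicase gene SGS1 rose by 2.19 ± 0.15 and RAD50, of double-strand break repair, by 2.11 ± 0.14. COS10, a subtelomeric gene, fell by 2.89 ± 0.15 and DAL80, a repressor of nitrogen genes, by 2.46 ± 0.15. Of 5495 genes, 4092 passed. Of 684 genes of 3000 bp and over 454 rose and 107 fell (455 and 107 adjusted over the list alone; adjusted p = 9.56e-34, and adjusted p = 0.0782 with an estimated correlation). Among 1587 genes under 1000 bp 31 rose and 1222 fell (32 and 1230 adjusted over the list alone; adjusted p = 1.51e-14, and adjusted p = 0.145 with an estimated correlation). Among 2158 genes of 1000 to under 2000 bp 345 rose and 1156 fell (341 and 1150 adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.421 with an estimated correlation). Among 1066 genes of 2000 to under 3000 bp 458 rose and 319 fell, the same adjusted over the list alone (adjusted p = 1.38e-07, and adjusted p = 0.0903 with an estimated correlation).

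The list tests did not match genes on tract length, with which the calls in set2 changed. List and length were thus not told apart. Of the 8 initiation reporters 7 rose in set2, the same adjusted over the list alone (adjusted p = 1.60e-05, and adjusted p = 0.0782 with an estimated correlation). VPS72 rose by 1.75 ± 0.19, SMC3 by 1.49 ± 0.12, AVO1 by 1.36 ± 0.09 and STE11 by 1.25 ± 0.09. PCA1 rose by 0.78 ± 0.10, SYF1 by 0.63 ± 0.11 and SPB4 by 0.52 ± 0.13, though SPB4 stood at -0.015 in AcH4 over input alone. OMS1 (0.25 ± 0.16) was not called, but passed at 0.42 with normexp, 0.38 with dim probes left out and 0.49 with medians of probes, and stood at -0.10 in AcH4 over input alone. Of 27 chromatin remodeler genes 17 rose and 4 fell, the same adjusted over the list alone (adjusted p = 4.12e-07, and adjusted p = 0.101 with an estimated correlation). HIR3, of a histone chaperone complex, rose by 1.87 ± 0.13 and INO80 by 1.82 ± 0.16. G1/S genes (13 up and 10 down of 31) and G2/M genes (7 up and 6 down of 17) lay above other genes, with the same counts adjusted over the list alone. Their adjusted p were 0.00299 and 0.0426, and adjusted p = 0.0903 and 0.299 with an estimated correlation. POL2 stood at 1.90 ± 0.10, RAD53 at 1.57 ± 0.11 and the myosin gene MYO1 at 1.38 ± 0.16. Of 132 ribosomal protein genes 121 fell and 0 rose, the same adjusted over the list alone (adjusted p = 2.36e-08, and adjusted p = 0.188 with an estimated correlation). RPL9B stood at -1.52 ± 0.20 and RPL8B at -1.47 ± 0.18. Glycolysis (17 down and 1 up of 19, with GLK1 at -1.36 ± 0.18) and respiration (29 down and 1 up of 35, with COX12 at -1.51 ± 0.19) fell, the same adjusted over the list alone (adjusted p = 0.00267 and 0.00578, and adjusted p = 0.255 and 0.161 with an estimated correlation). Pheromone genes (26 down and 1 up of 29), meiosis and sporulation genes (33 down and 6 up of 47, 33 and 8 adjusted over the list alone) and PAU and COS genes (19 down and 1 up of 23) fell, but the medians of these 3 lists against all genes turned from -0.57, -0.39 and -0.54 to 0.24, 0.14 and 0.22 with normexp. Their adjusted p were 0.0006, 0.00299 and 0.00395, and adjusted p = 0.367, 0.381 and 0.275 with an estimated correlation. All 7 histone genes fell, the same adjusted over the list alone, with HTA2 at -1.09 ± 0.17, but the list did not differ from other genes in camera (adjusted p = 0.0974). The Set2 and Rpd3S pathway had 4 up and 5 down of 14, the same adjusted over the list alone, with RCO1 at 1.40 ± 0.14 and SAP30 at -0.92 ± 0.20, and did not pass (adjusted p = 0.578). Genes within 20 kb of a chromosome end had 40 up and 100 down of 168, the same adjusted over the list alone, and did not pass (adjusted p = 0.116), and their median against all genes turned from -0.14 to 0.19 with normexp.

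**Figure D2:**
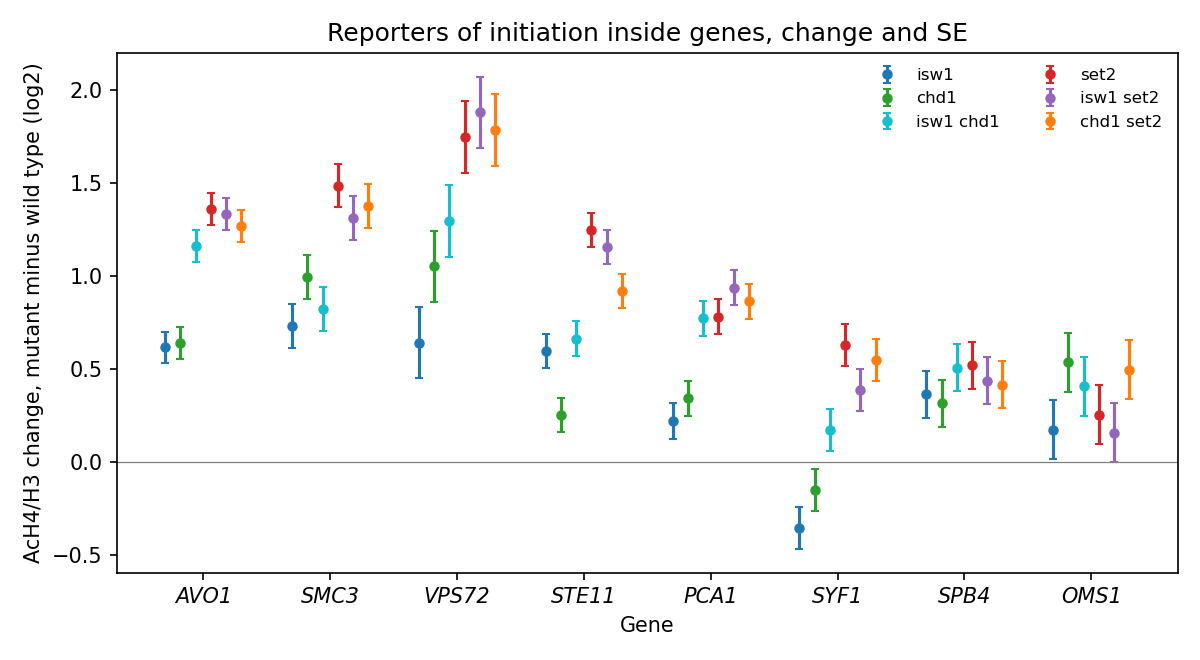
Change in AcH4 per H3 from wild type (log2, vertical axis) at the 8 measured reporters of initiation inside genes (horizontal axis) in the 6 mutant strains, with points for the fitted change and bars of 1 SE. AVO1 lay at 0.62 in isw1 and 1.36 in set2, and SYF1 lay at -0.36 in isw1 and -0.15 in chd1, while OMS1 (0.17) and PCA1 (0.22) in isw1 turned below 0 with loess and SPB4 in AcH4 over input alone lay at -0.14 in isw1 chd1, -0.015 in set2 and -0.00069 in isw1 set2.

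Along genes 2654 of the 4986 tracts in set2 gained in the 3' part against the 5' part and 259 lost. In the profile the 5' part itself changed by -0.49 and the 3' part by 0.17. In the 3' minus 5' difference NPR2 gained 3.18 ± 0.29, the drug pump gene PDR15 3.11 ± 0.23 and IFM1, a mitochondrial initiation factor gene, 3.09 ± 0.23. The proteasome gene SEM1 changed by -2.70 ± 0.23. The median change was 0.18 for tracts under 1000 bp, 0.57 for 1000 to under 2000 bp, 1.06 for 2000 to under 3000 bp and 1.11 for 3000 bp and over. H3 was called at 2198 genes, 853 up and 1345 down (1092 and 866 with quantile normalization), and at 1322 without wild type replicate 2. FIG2 gained H3 by 2.09 ± 0.12 and AGA1 also gained it (0.77 and 0.73 with normexp), and LCL1 (-1.80 ± 0.21) and REX4 (-1.29 ± 0.12) lost it. In AcH4 per H3 FIG2 fell by 1.95 ± 0.18 and AGA1 by 1.78 ± 0.18, but FIG2 stood at 0.13 with normexp and at 0.14 in AcH4 over input alone, and AGA1 at -0.063 and -0.28, with no call at either gene. The total of 2913 tracts was 1388 over the genes with an upstream tract of their own, a smaller set chosen after seeing the data.

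In the isw1 set2 strain CCH1 rose by 2.24 ± 0.14 (log2, SE, n = 3), NFT1 by 2.23 ± 0.15 and the polarity gene BUD6 by 2.20 ± 0.15. The alcohol dehydrogenase gene ADH7 (-2.58 ± 0.15), AGA1 (-2.57 ± 0.18) and FIG2 (-2.54 ± 0.18) fell. With normexp AGA1 (-0.24) and FIG2 (-0.077) were not called. Of 29 pheromone genes 28 fell and 1 rose, the same adjusted over the list alone (adjusted p = 5.00e-06, and adjusted p = 0.255 with an estimated correlation), but their median against all genes turned from -0.88 to 0.12 with normexp. Of 132 ribosomal protein genes 130 fell, the same adjusted over the list alone, with RPL9B at -1.62 ± 0.20 (adjusted p = 1.78e-10, and adjusted p = 0.149 with an estimated correlation). Of the 8 initiation reporters 7 rose, the same adjusted over the list alone (adjusted p = 4.67e-05, and adjusted p = 0.0782 with an estimated correlation). VPS72 rose by 1.88 ± 0.19, AVO1 by 1.34 ± 0.09, SMC3 by 1.31 ± 0.12 and STE11 by 1.16 ± 0.09. PCA1 rose by 0.94 ± 0.10, SPB4 by 0.44 ± 0.13 and SYF1 by 0.39 ± 0.11, though SPB4 stood at -0.00069 in AcH4 over input alone. OMS1 stood at 0.15 ± 0.16 and was not called. It passed as a rise with normexp (0.44) and with dim probes left out (0.36) and as a fall in AcH4 over input alone (-0.25), and was -0.053 with equal array spread and -0.21 in the series value table. In all 4208 of 5494 genes passed, 1321 up and 2887 down. H3 was called at 2028 genes, 784 up and 1244 down (1084 and 872 with quantile normalization), and at 1250 without wild type replicate 2. It rose over FIG2 (1.11 ± 0.12), AGA1 (0.88 ± 0.13) and RDS1, a zinc cluster regulator gene (0.87 ± 0.07), with FIG2 at 0.67 and AGA1 at 0.59 with normexp. In the 3' part against the 5' part 2663 tracts gained and 268 lost, with PDR15 at 3.39 ± 0.23 and AGP2 at 3.19 ± 0.21. In the profile the 5' part itself changed by -0.51 and the 3' part by 0.14.

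The isw1 by set2 interaction passed at 540 genes, 66 up and 474 down (341 and 702 in AcH4 over input alone). It was low over AAD3, an aryl alcohol dehydrogenase gene (-3.00 ± 0.17, SE, n = 3 per strain; chromosome 3, 313492 to 314925), and its neighbour RDS1 (-1.86 ± 0.13), and high over DAL80 (1.28 ± 0.22) and AIF1 (1.16 ± 0.17). The total was 182 with loess, 220 with quantile normalization and 297 with equal array spread.

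In the chd1 set2 strain NFT1 rose by 2.30 ± 0.15 (log2, SE, n = 3), SGS1 by 2.26 ± 0.15, CCH1 by 2.20 ± 0.14 and ADY3 by 2.10 ± 0.16. AGA1 (-3.12 ± 0.18), FIG2 (-2.95 ± 0.18), STE3, the a-factor receptor gene (-2.71 ± 0.15; chromosome 11, 113330 to 115370), and the carnitine transferase gene YAT1 (-2.40 ± 0.30) fell. With normexp AGA1 (-0.27), YAT1 (-0.28) and FIG2 (0.055) were not called. All 8 initiation reporters rose, the same adjusted over the list alone (adjusted p = 4.20e-05, and adjusted p = 0.0782 with an estimated correlation). They ran from SPB4 (0.42 ± 0.13) and OMS1 (0.50 ± 0.16) to SMC3 (1.38 ± 0.12) and VPS72 (1.79 ± 0.19). SYF1 rose by 0.55 ± 0.11, PCA1 by 0.86 ± 0.10, STE11 by 0.92 ± 0.09 and AVO1 by 1.27 ± 0.09. The calls of OMS1 and SPB4 were lost in 5 and 2 of 20 alternatives. In AcH4 over input alone they stood at 0.00024 and 0.012, with medians of probes SPB4 stood at 0.27, and OMS1 stood at 0.32 with equal array spread, 0.19 in the value table, 0.35 without wild type replicate 2 and 0.38 without chd1 set2 replicate 1. Of 47 meiosis and sporulation genes 37 fell and 8 rose, the same adjusted over the list alone (adjusted p = 0.00239, and adjusted p = 0.377 with an estimated correlation), but their median against all genes turned from -0.51 to 0.16 with normexp. SPO77 stood at -2.10 ± 0.16 and the kinase gene SMK1 at -1.93 ± 0.16. Of 132 ribosomal protein genes 103 fell, the same adjusted over the list alone (adjusted p = 2.79e-05, and adjusted p = 0.299 with an estimated correlation). In all 4219 of 5494 genes passed, 1349 up and 2870 down. H3 was called at 2207 genes, 894 up and 1313 down (1131 and 913 with quantile normalization), and at 1284 without wild type replicate 2, with FIG2 at 2.08 ± 0.12 and AGA1 at 1.64 ± 0.13 (0.74 and 0.72 with normexp). In the 3' part against the 5' part 2862 tracts gained and 316 lost. In this difference PDR15 stood at 3.61 ± 0.23, AGP2 at 3.55 ± 0.21 and SEM1 at -2.85 ± 0.23. In the profile the 5' part itself changed by -0.56 and the 3' part by 0.17.

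The chd1 by set2 interaction passed at 1153 genes, 358 up and 795 down (412 and 352 with quantile normalization, 120 and 539 with equal array spread, 127 and 590 in the series value table, 1162 and 1074 in AcH4 over input alone). It was low over PRM4, a pheromone-regulated gene (-1.96 ± 0.35, SE, n = 3 per strain), and ADY3 (-1.74 ± 0.23), and high over GIT1, a glycerophosphoinositol transporter gene (1.24 ± 0.13), and ADE12 (1.12 ± 0.18). The total was 269 with loess and 2025 without chd1 replicate 3.

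**Figure D3:**
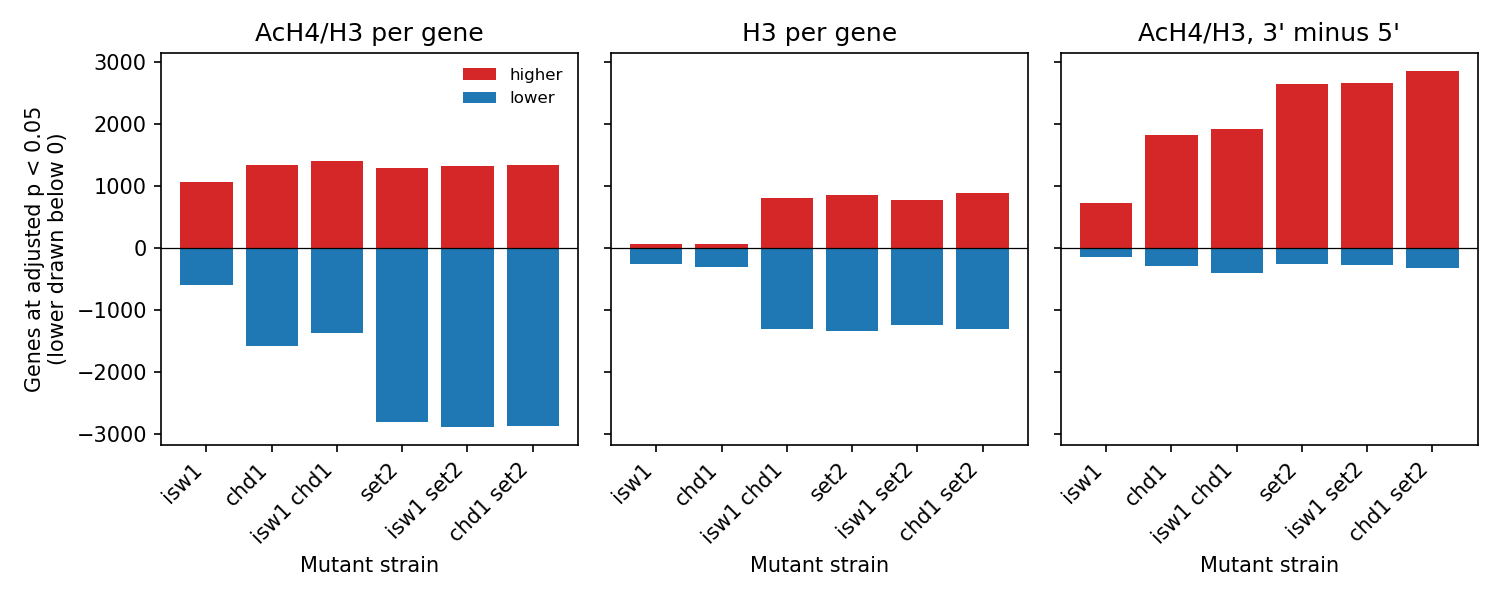
Number of genes with adjusted p under 0.05 against wild type (vertical axis) for AcH4 per H3, H3 and the 3' minus 5' difference in each mutant strain (horizontal axis), with higher genes above 0 and lower genes below. H3 calls numbered 329 in isw1 and 381 in chd1 and between 2028 and 2207 in the other 4 strains, and with the scan session as a block isw1 and chd1 had 26 and 33.

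The changes in the 6 mutants overlapped. In set2 and isw1 set2, AcH4 per H3 rose in both at 1220 genes and fell in both at 2676, where independent lists would share 310 and 1473. The changes correlated with r = 0.97 across genes, which are not independent replicates. In isw1 and chd1, 761 genes rose and 517 fell in both, where independent lists would share 259 and 173 (r = 0.77). Over the 15 pairs of mutants r ran from 0.59 to 0.97. It was lowest in isw1 and set2, where 727 genes rose and 547 fell in both, against 249 and 308 for independent lists, and 138 were called in opposite directions. In all 6 mutants 558 genes rose and 410 fell, where independent lists would share 0.913 and 6.06. Unchanged groups simulated against the same wild type arrays gave r between 0.50 and 0.51. They shared 0 calls, but groups without change have few calls to share, so that count is no baseline. The covariance was 0.549 for set2 and isw1 set2 against 0.0126 simulated, 0.149 for isw1 and chd1 against 0.0128, and 0.164 for isw1 and set2 against 0.0128. With 3 wild type replicates the controls could not be divided into equal parts. The simulated covariance holds the replicate noise of the shared controls. A feature common to all wild type arrays, such as their scan sessions, could still be part of the excess.

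**Figure D4:**
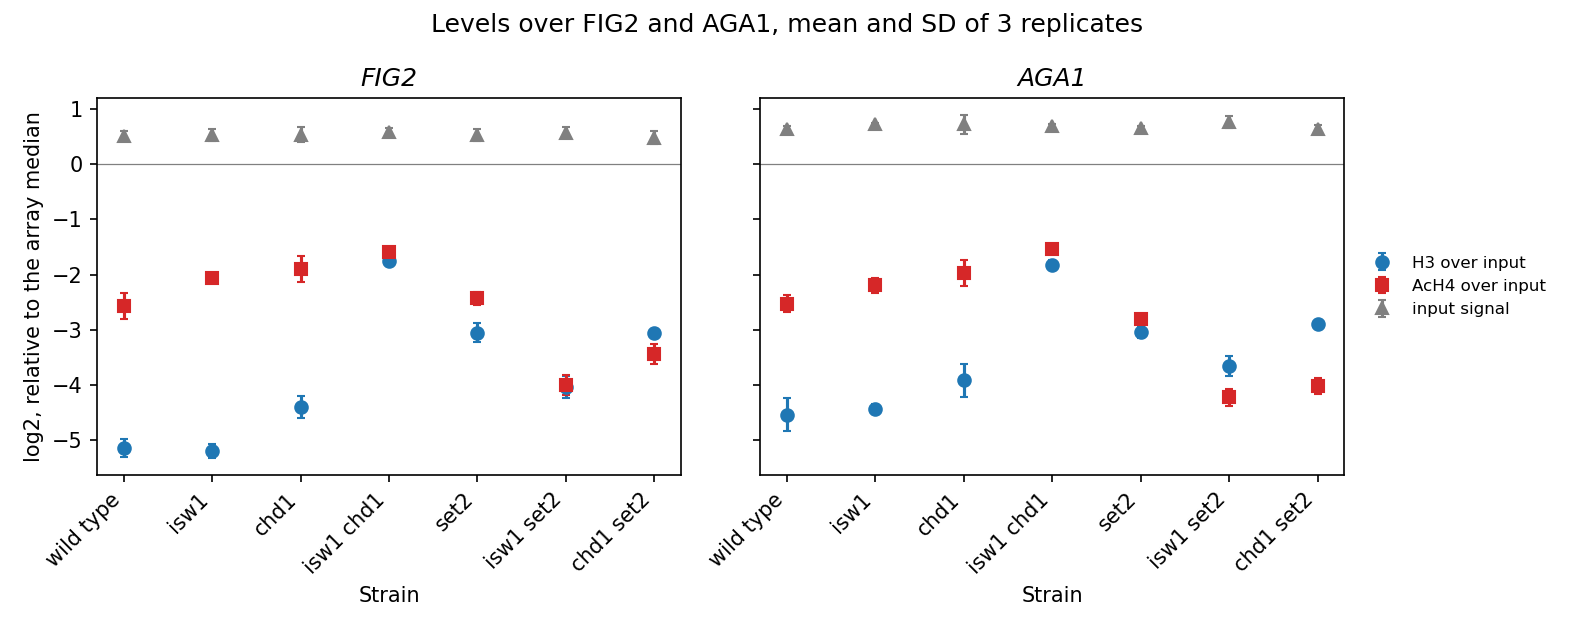
Levels over FIG2 and AGA1 (log2 relative to the array median, vertical axis) of H3 over input, AcH4 over input and the input signal of the H3 arrays in the 7 strains (horizontal axis), with points for means of 3 replicates and bars of 1 SD. H3 over FIG2 lay at -5.14 ± 0.16 in wild type and -1.75 ± 0.09 in isw1 chd1, while the input lay at 0.51 ± 0.09 and 0.57 ± 0.07, and the rise of 3.39 was 0.93 with normexp.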

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

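Tests of the splits with strain effects removed, of the probe level in isw1, chd1 and isw1 chd1, of the scan sessions and of contrasts between mutants were chosen only after the result was seen. In 3 results the change in a double mutant differed from the sum of the single changes, by a test of that difference. The isw1 by chd1, isw1 by set2 and chd1 by set2 interactions passed at 1633, 540 and 1153 genes, which 1, 10 and 10 of 100 splits of the samples matched, the real one included, with 1486, 3338 and 3091 genes as the highest others. Splits that mix strains carry the changes of the single mutants (1667 genes in isw1, 2913 in chd1 and 4092 in set2) into the interaction, so these counts do not show whether chance can be excluded. With the additive strain effects removed before regrouping, 1, 1 and 2 of 100 splits matched, the real one included, with 1539, 88 and 1729 genes as the highest others. All 3 shares lie under 0.05, which argues against chance only if arrays can be exchanged between strains. Scan sessions differed between strains and a session term could not be fitted for the interactions, so session is not excluded as their source. For the 18 comparisons of 1 mutant with wild type, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts ran from 329 to 4219. The highest other counts in chd1 were 78 for AcH4 per H3, 26 for H3 and 106 for the 3' minus 5' difference, 4 and 5 for H3 in isw1 chd1 and chd1 set2, and 0 elsewhere.

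In the input channel, which the comparisons use only as a reference, the set2 strain lacked signal over chromosome 9, 324768 to 336218, next to BAR1, with a mean of -6.31 over 61 probes and 6 arrays against -0.16 to -0.06 in the other 6 strains. The stretch holds YIL014C-A, MNT3, PDR11, TIR3, DOT5 and part of EST3. Results that use the set2 strain, both set2 interactions included, therefore do not separate the loss of SET2 from the lack of this stretch. The isw1 set2 and chd1 set2 strains had input there, and their changes in AcH4 per H3 correlated with those in set2 with r = 0.97 and 0.95.

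The rise of AcH4 per H3 in the 3' part against the 5' part appeared in all 6 mutants, whose AcH4 values spread less than those of wild type, which could pull low 3' values up. Among probes matched on wild type level the change went from 0.81 to 0.38 in set2, 0.79 to 0.32 in isw1 set2, 0.91 to 0.41 in chd1 set2, 0.46 to 0.14 in chd1, 0.49 to 0.20 in isw1 chd1 and 0.21 to 0.027 in isw1, so most of it went with that level. What was left exceeded the change of wild type arrays shrunk to the same spread by at least 0.27 in every replicate of the 3 set2 strains and by at least 0.0779 in chd1 and isw1 chd1, which argues against a narrower spread as the whole cause there, while in isw1 the lowest replicate gave -0.00587 and it stays open. Pairs of mutants from different AcH4 sessions differed by a mean of 0.47 (isw1 set2 minus isw1), 0.40 (chd1 set2 minus chd1) and 0.18 (isw1 chd1 minus isw1), but also by 0.020 (isw1 chd1 minus chd1), 0.080 (chd1 set2 minus set2) and -0.014 (isw1 set2 minus set2), the pair within a session by -0.094 (isw1 set2 minus chd1 set2, 82 tracts called), and as a session term could not be fitted, session and strain cannot be told apart. The change per H3 is the AcH4 change less the change in H3, the denominator. Lower H3 over the 3' part, relative to the array median, thus made up the rest of the 3' rise, and all of it in chd1 set2. H3 over the 3' part lay between -0.13 and -0.11 on the chd1 arrays and between -0.02 and 0.09 on those of wild type. Why H3 was lower was not tested. The 3' rise was smaller in AcH4 over input alone. There the 3' part changed by 0.081 in isw1, 0.024 in chd1 and 0.036 in isw1 chd1, against 0.15, 0.18 and 0.22 per H3. It changed by 0.069 in set2, 0.036 in isw1 set2 and -0.037 in chd1 set2, against 0.17, 0.14 and 0.17. The 5' part changed there by -0.51 to -0.046 in all 6 mutants. The brightness of the AcH4 arrays also differs between strains and its effect was not tested, so it stays open beside loss of the factors named by the labels, an untested biological explanation.

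H3 calls numbered 2028 to 2207 in isw1 chd1 and the 3 set2 strains, against 329 in isw1, with 1 H3 array in the wild type session, and 381 in chd1, which shares no session with wild type H3 arrays either. Within a session 15 genes differed between isw1 set2 and set2, 302 differed between chd1 set2 and set2 and 246 between isw1 set2 and chd1 set2, which share a session in part, and 308 to 641 differed in 4 pairs of mutants that share none. Crossing sessions thus did not by itself bring as many calls, but no pair tests the session of wild type apart from strain, so session and strain cannot be told apart. The input channel is also open. Across genes the H3 change correlated with the input change with r of at most -0.23 and as low as -0.46 in these 4 strains, between the bounds set for either answer. In isw1 and chd1, with fewer H3 calls, r was -0.65 and -0.53. The input is the denominator of the H3 value, so a negative r can arise from noise in the input alone and cannot decide the question. The loss of Set2 or of both remodelers stays open too.

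H3 over FIG2 and AGA1 rose by 0.62 to 3.39 in 5 mutants, and by 0.35 to 0.93 with normexp, where the 2 calls in chd1 were lost. In wild type H3 lay at -5.14 ± 0.16 over FIG2 and -4.54 ± 0.30 over AGA1 (SD, n = 3), far below the array median. The size of the rise thus changed with the background correction, and the effect of so low a signal was not tested further. A fall of the input, the denominator, would have to be of similar size, but the largest fall was -0.0156 of the rise, which argues against the input channel. H3 arrays of isw1 set2 and set2, which shared a session, differed over FIG2 by -0.98 ± 0.12 (SE, n = 3) and over AGA1 by -0.62 ± 0.13. With normexp the differences were -0.097 ± 0.15 and -0.14 ± 0.15 and did not pass the test, so the scan session cannot be told apart from strain here. Cross-hybridisation between the 2 genes, which have related sequences, was not tested and stays open beside a strain effect.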

How the results depend on the processing

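The fits with equal array spread for the profile, the genes with an upstream tract of their own and the genes with missing input left out were chosen after seeing the data. Over 21 counts and 443 alternatives, 363 stayed within 1.5 times and 80 moved. AcH4 per H3 in isw1 chd1, set2, isw1 set2 and chd1 set2 stayed within 1.5 times under every alternative run (1951 to 3471, 3347 to 4535, 3528 to 4627 and 3522 to 4590). Of 5052 alternatives of 250 gene values, 4875 kept direction and side of the threshold, 147 lost the call, 11 gained it and 19 reversed. Unless stated, the cause was not tested. Depth on arrays is signal over background, and leaving out dim input probes moved no count by over 1.5 times.

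AcH4 per H3 in isw1 (1667) was 565 with loess, 988 with quantile normalization, 757 with equal array spread and 931 in the value table, and in chd1 (2913) 1512 with loess and 1784 with equal spread. H3 in isw1 (329) and chd1 (381) was 209 and 251 with normexp, 168 and 227 in the value table, 130 and 134 with medians of probes, 546 and 875 with the session as a random block (consensus correlation -0.08), 26 and 33 with session or date as a fixed block, and 22 and 20 with the compared strains alone (fewer samples). H3 in isw1 was 177 with loess and 4 within session 1 (fewer samples, the lone array assumed to vary like the others). Medians of probes gave 1371, 1310 and 1461 H3 calls in isw1 chd1, isw1 set2 and chd1 set2, with 666 up and 644 down in isw1 set2, 756 and 705 in chd1 set2 and 743 and 742 in set2. The isw1 by chd1 interaction (1633) was 741 with loess, 952 with equal spread and 2785 in AcH4 over input alone. The isw1 by set2 interaction (540) was 182 with loess, 220 with quantile, 297 with equal spread, 350 in the value table and 1043 in AcH4 alone. The chd1 by set2 interaction (1153) was 269, 764, 659, 717 and 2236 in the same order. The 3' minus 5' count in isw1 (871) was 226 with loess, 446 with quantile, 304 with equal spread and 362 in the value table, in chd1 (2111) 1166, 1404, 1357 and 1334, and in isw1 chd1 (2328) 1522 with loess. Over genes with an upstream tract of their own (fewer genes tested) the 6 counts were 356, 973, 1101, 1388, 1376 and 1489.

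Leaving out each replicate gave, for AcH4 per H3, 1093 (without isw1 replicate 3) to 1557 in isw1, 2190 to 3329 in chd1, 2430 to 2587 in isw1 chd1, 3870 to 4043 in set2, 3961 to 4118 in isw1 set2 and 4005 to 4147 in chd1 set2. H3 gave 14 to 973 in isw1, 50 to 1086 in chd1, 1145 to 2338 in isw1 chd1, 1322 to 2384 in set2, 1250 to 2275 in isw1 set2 and 1284 to 2439 in chd1 set2, each lowest without wild type replicate 2 and highest without wild type replicate 3. The isw1 by chd1 interaction ran from 1021 (without chd1 replicate 1) to 2460 (without chd1 replicate 3), isw1 by set2 from 397 to 601 and chd1 by set2 from 837 to 2025 (without chd1 replicate 3). The 3' minus 5' counts ran from 485 (without isw1 replicate 3) to 810 in isw1, 1461 to 2487 in chd1, 2015 to 2201 in isw1 chd1, 2660 to 2857 in set2, 2678 to 2868 in isw1 set2 and 2929 to 3111 in chd1 set2. The isw1 counts also moved without isw1 replicate 1 (576), wild type replicate 2 (567) and, for H3, without wild type replicate 1 (65) and isw1 replicates 1, 2 and 3 (123, 73 and 147). H3 in chd1 was 177 without wild type replicate 1 and 188 and 189 without chd1 replicates 1 and 2.

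The fits treated the replicate numbers as unpaired. Every strain's AcH4 and H3 arrays correlated best with their own number in 21 of 21 pairs, as a hint from the data. But 1 pair (wild type replicate 2) had r = 0.07, under the limit of 0.1. The profile values, and the rule that every mutant replicate lie beyond every wild type replicate in AcH4 per H3, did use AcH4 minus H3 of the same number. With the replicate block the counts were 2510 for AcH4 per H3 in isw1, 1857 for its 3' minus 5' difference, and 2498, 992 and 1938 for the interactions in the order above, and the others stayed within 1.5 times. PCA1 in isw1 gained its call there (0.22). The split was 236 up and 756 down for isw1 by set2 and 819 and 1119 for chd1 by set2. Of the lists, 13, 12, 11, 14, 13 and 13 passed in camera (isw1, chd1, isw1 chd1, set2, isw1 set2, chd1 set2) and 0 with an estimated correlation in each (camera), while fry passed 19 in chd1, 20 in isw1 set2 and 21 in chd1 set2. With AcH4 over input alone 11, 9, 8, 13, 11 and 12 passed. Genes called one way in all 6 mutants numbered 968 and, at 0.01, 572. The 3' part in chd1 set2 turned to -0.037 in AcH4 over input alone, and the 5' part in isw1 turned from -0.03 to 0.0086 with genes of at least 1000 bp and to 0.027 with equal spread. Reversed genes under normexp were AGA1 in isw1 chd1 (0.0068) and FIG2 in set2 (0.13) and chd1 set2 (0.055). In isw1 PCA1 was -0.028 with loess and OMS1 -0.14 with loess, -0.023 with quantile normalization and -0.045 in AcH4 over input alone. In isw1 set2 OMS1 was -0.053 with equal spread and -0.21 in the value table. In AcH4 over input alone FIG2 and AGA1 were 0.97 and 0.99 in isw1 chd1, FIG2 was 0.14 in set2, OMS1 was -0.026, -0.10 and -0.25 and SPB4 -0.14, -0.015 and -0.00069 in isw1 chd1, set2 and isw1 set2. SYF1 in chd1 ran from -0.27 (without chd1 replicate 3) to 0.0044 (without chd1 replicate 1).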

Other observations

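The comparisons of H3 over gene lists and along genes, of FLO8, between mutants and of the end of chromosome 3 were chosen only after the data were seen. H3 itself passed in camera over 30 of 132 pairs of a list and a mutant, and over 0 with an estimated correlation (adjusted p = 0.723 for each pair below). The 6 with the lowest adjusted p were as follows. In isw1 chd1 H3 rose at 12 of 29 pheromone response genes and fell at 0 (13 and 0 adjusted over the list alone; adjusted p = 2.45e-08), with a median 0.26 above that of all genes, rose at 13 of 19 glycolysis genes and fell at 0, the same adjusted over the list alone (adjusted p = 2.32e-06), and rose at 21 of 41 amino acid synthesis genes and fell at 1 (25 and 2 adjusted over the list alone; adjusted p = 2.32e-06). In chd1 set2 it fell at 264 of 683 genes of 3000 bp and over and rose at 26 (268 and 26 adjusted over the list alone; adjusted p = 9.80e-06), and rose at 18 of 41 amino acid synthesis genes and fell at 0, the same adjusted over the list alone (adjusted p = 6.14e-05). In isw1 set2 it rose at 43 of 132 ribosomal protein genes and fell at 10 (44 and 10 adjusted over the list alone; adjusted p = 1.16e-05). Of 26 chromatin remodeler genes, H3 fell at 14 and rose at 2 in chd1 set2, the same adjusted over the list alone (adjusted p = 0.000853). These directions held under all 6 scalings run. In the last of 10 bins along gene tracts H3 over input averaged -0.01 ± 0.15 in wild type (SD, n = 3), -0.13 ± 0.01 in isw1, -0.33 ± 0.03 in chd1, -0.40 ± 0.01 in isw1 chd1, -0.32 ± 0.05 in set2, -0.28 ± 0.03 in isw1 set2 and -0.49 ± 0.07 in chd1 set2, values that were not tested.

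FLO8, an adhesion regulator used as a reporter of initiation inside genes, is marked as a pseudogene in the name table and so fell outside its list. Over its 22 probes (chromosome 5, 375229 to 378783) AcH4 per H3 rose by 0.48 ± 0.13 in isw1 (SE, n = 3), 0.97 ± 0.13 in isw1 chd1, 0.76 ± 0.13 in set2, 0.66 ± 0.13 in isw1 set2 and 0.55 ± 0.13 in chd1 set2, with adjusted p from 2.18e-07 to 0.00588, and stood at 0.26 ± 0.13 in chd1 (adjusted p = 0.0904). Between mutants, isw1 set2 differed from set2 in AcH4 per H3 at 96 genes and chd1 set2 from set2 at 323, and isw1 set2 differed from isw1 at 3804 and chd1 set2 from chd1 at 3106. The AcH4 arrays of each pair were scanned in different sessions.

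At the right end of chromosome 3 (302302 to 314925) AcH4 per H3 was low in isw1 set2 over 6 adjacent genes, EMA35, YCR101C, YCR102C, ADH7, RDS1 and AAD3, by -1.37 to -2.58. The isw1 by set2 interaction averaged -1.71 over them, and 0 of 5408 other runs of 6 genes was as low (lowest -0.74). Beside AAD3 and RDS1, the other 4 each passed the interaction test (adjusted p at most 0.0213). The input changed by -0.21 to 0.14. H3, the denominator, was higher than in wild type over all 6 by 0.16 to 0.87, and passed the test at YCR101C (0.43), ADH7 (0.42), RDS1 (0.87) and AAD3 (0.38). The stretch was not uniform in the single mutants. In set2 alone AcH4 per H3 stood at -1.67 over ADH7, -1.05 over YCR101C and -0.59 over YCR102C. It stood there at -0.40 over RDS1, -0.21 over EMA35 and 0.24 over AAD3. In isw1 alone YCR102C stood at 1.22, which enters its interaction. A candidate explanation is that the stretch depends in part on Isw1 where Set2 is absent, a hypothesis found and tested on the same data. A feature of the single isw1 set2 strain may equally account for it.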
